A study of Mus musculus with 2 samples.

How the data were processed

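T cells were enriched from B16 melanoma tumours of mice at day 14 by positive selection of CD3-bearing cells after a Percoll step, per the labels' protocols. Wild-type cells and cells lacking Nr4a genes were stained with hashtag antibodies, pooled and loaded into a single BD Rhapsody capture of about 20000 cells, and cDNA was amplified by TAS-Seq, a terminal-transferase method for bead-bound cDNA. The 2 samples of the series are the mRNA library and the hashtag library of that capture. The labels list 6 hashtags and do not say which of them marks which genotype, and the cell names in the mRNA table are plain barcode numbers without a hashtag. The comparison of genotypes and the check of cell names against hashtag counts, both planned before the data were examined, therefore could not be run, and each hashtag was treated as a sample of unknown group.

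Both deposited tables hold whole-number counts, of genes per cell barcode and of hashtags per barcode. Reads were aligned to GRCm38 and the tools named are cutadapt 2.10, Bowtie2 2.3.4.1 and 2.4.2 and R 3.5.3, per the submitters' processing notes, which give no role for each. Whether the authors collapsed the counts by molecular identifier is not given in the sources used here. The design had assumed such molecules, but the median non-zero value of the deposited counts was 7 and 56.1% of non-zero values were above 5, so they were treated as reads: 10 counts were taken in place of 1 molecule in every minimum of the design, and a gene was scored as present in a cell at 5 or more counts. These conversions were set after the values had been seen. Intervals and floors therefore cover counting error only, and reads of 1 molecule are not independent.

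The mRNA table held 27635 genes and 12016 barcodes with 629041564 counts. Barcodes with under 500 genes (279) or over 25% mitochondrial counts (675) were removed, which left 11318. Counts were scaled to 10000 per cell, log-transformed and reduced to 3000 variable genes with scanpy 1.11.5 and anndata 0.12.19. A shared-neighbour graph from 40 principal components and 20 neighbours was clustered by the Leiden method at a resolution of 1 (0.5 and 1.5 as alternatives) with leidenalg 0.10.2 and igraph 0.11.9. Clusters were named from 17 marker lists fixed before the data were examined, leaving out those of CD8, CD4 and regulatory T cells. A name needed at least 3 markers detected in 20% of the cells. For classes other than T cells, a marker also had to be among the 30 genes with the highest fold. The class with the highest mean marker ratio gave the name. A cluster with 5 T cell markers and fewer than 3 of any other class was named T cell-like whatever its ratio, which named cluster 1. A cluster with T cell markers but 3 markers of another class stayed unnamed, and so did a shallow cluster with no marker among its leading genes. The unnamed cells included cluster 18, led by Ace, Ear2 and Treml4, with Trac in 66.0% and Tyrobp in 84.9% of its cells. The naming rule and the quality limits were set after the data had been seen. Scrublet, run through scanpy, marked 0 cells at its automatic threshold of 0.641, so the 5% of cells with the highest scores (546) were removed as an alternative only. Further computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

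The hashtag table held 14 hashtag columns, 545188 barcodes and 21923976 counts, of which 16.9% lay on barcodes of the mRNA table. The background mixture was taken from barcodes outside the mRNA table with under 10 hashtag counts, over 12 hashtags; A0313 and A0314, with almost no counts, were left out of the model. A cell was called for a hashtag when adding that hashtag raised the log likelihood by at least 3 over the background and by at least 3 more than any other hashtag, and when no other hashtag reached 3. Hashtag A0301 made up 42.3% of the background and A0303 1.90%. On simulated T cell-like barcodes holding background alone, 4.16% were called, and with 30%, 60% and 90% of own hashtag the calls were right in 97.5%, 99.5% and 99.9%.

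Gates were set within T cell-like clusters. CD8 cells had Cd8a or Cd8b1 and no Cd4 at the gate, and CD4 cells the reverse. The Tcf7-positive arm had Tcf7 without Havcr2, the Havcr2-positive arm the reverse, and CD4 cells were split by Foxp3. Counts were summed per hashtag and arm for hashtags with at least 30 cells in both arms, scaled to the same total (CPM), and compared as log2 ratios within each hashtag after adding 5 counts to each sum. Genes with a mean of at least 100 counts per sum were examined. A gene was called higher or lower when every hashtag gave the same sign and the median log2 ratio was at least 1 in size. No p-value was computed, because cells are not replicates and hashtags of unknown genotype are not replicates of a group; shares of cells carry exact binomial intervals at 95%. The named genes are the 10 highest and 10 lowest median ratios among called genes with at least 40 counts in each arm, leaving out gate genes, antigen receptor segments and mitochondrial genes, together with the 2 to 4 largest ratios of each of 15 gene lists fixed before the data were examined; 3 genes that met this rule are not named in the texts or drawn in the figures. A ratio with an arm at or under 30 counts is given as a bound against that floor, over the sum of the hashtags used, unless the median over hashtags or all cells pooled gave a smaller ratio, in which case these ratios are given. Of 189 genes in the lists, 188 were found in the table.

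The comparison was tested on simulated data. With arms shuffled, 31 of 5915 genes were called for Tcf7-positive against Havcr2-positive cells, 48 of 3781 for Foxp3-positive against Foxp3-negative cells and 23 of 7517 for CD8 against CD4 cells. Of 50 genes changed by a log2 of 1, 2, 3 and 4, the share called was 26%, 96%, 98% and 100% in the first comparison. It was 48%, 98%, 100% and 100% in the second, and 50%, 94%, 96% and 100% in the last. The changed genes were scored at the lower minimum of 10 counts instead of 100. Genes pushed under 100 could thus still be called, and these shares may exceed those of the comparison itself.

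Alternatives planned before the data were examined were median-of-ratios scaling, a lower expression minimum (10 counts), a gate at 10 counts, thinning of each cell to 8000 counts, removal of cells with Mki67 or Top2a, removal of likely doublets, no quality filter, counts pooled over hashtags, each hashtag left out, gates on any cell with Cd3 counts, Slamf6 in place of Tcf7, all Tcf7-negative cells as the other arm, and other clustering resolutions. Added after seeing the data were pooling of all cells, a gate at 1 count, hashtag calls at a log likelihood ratio of 5, hashtags with 10 or more cells per arm, removal of T cells with macrophage or melanoma counts, and a Tcf7-positive arm with Pdcd1. Gene positions are from the GENCODE annotation of GRCm38.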

Results

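Intratumoral CD3-selected cells of B16 melanoma, a transplantable mouse skin tumour line, were profiled in a single pooled capture of wild-type and Nr4a-deficient cells at day 14. The series concerns Tcf7-expressing (TCF1) precursors of exhausted CD8 T cells and the orphan nuclear receptors of the Nr4a family. The barcodes of the mRNA library held 4138 to 892142 counts each (median 25960.5), and 11318 passed the quality filter, against about 20000 cells loaded. Of these, 6158 could be called for 1 of 6 hashtags, 2105 for A0301, 379 for A0302, 620 for A0303, 546 for A0304, 1141 for A0305 and 1367 for A0306. Hashtag counts were shallow, with a median of 12 per cell, and only 45.3% of T cell-like cells were called, against 80.9% of macrophage-like and 83.2% of melanoma-like cells. The genotype behind each hashtag is unknown, so all values below are for hashtags or for arms within them, with no replicate test and no comparison of wild-type with Nr4a-deficient cells.

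T cell-like cells made up 69.7% of the cells (95% interval 68.8 to 70.5, 7887 cells), macrophage or monocyte-like cells 13.5% (12.8 to 14.1) and melanoma-like cells 8.97% (8.45 to 9.51). Dendritic cell-like cells were 2.32%, neutrophil-like cells 1.22%, gamma delta T cell-like cells 1.18% and fibroblast-like cells 0.230%, and 2.94% stayed unnamed. The T cell-like class included cluster 1 (1751 cells, median 15998 counts), whose leading genes were Klra7, Klra1 and Klra6, a receptor family shared with NK cells; at the gate Trac was found in 59.9%, Trbc2 in 78.4% and Cd3d in 61.0% of its cells and the NK cell gene Ncr1 in 1.20%, against 10.1%, 8.87%, 7.49% and 0 of melanoma-like cells (median 193426 counts). Cd3e was found in 32.7% of cluster 1, and Klrb1c and Tyrobp of the NK cell marker list in 9.94% and 10.5%. In melanoma-like cells these stood at 4.73%, 0.197% and 2.96%. In the deeper macrophage-like cluster 5 (median 58998 counts), however, Trac was found in 58.3%, Trbc2 in 59.1% and Cd3d in 53.1%. These genes alone thus do not settle what cluster 1 is. The class also included cluster 11 (252 cells, median 59575.5 counts), whose leading genes were Igha, Igkc and Jchain. Trac was found in 97.2%, Foxp3 in 87.3%, Igkc in 11.9% and Jchain in 0.397% of its cells. Leading genes were ranked by mean CPM, so few cells can place a gene among them. Over the 6 hashtags the T cell-like share ranged from 44.2% to 68.4% (median 52.5%), the macrophage-like share from 13.2% to 51.9% (median 19.7%) and the melanoma-like share from 0.968% to 26.5% (median 12.8%). Because the share of cells that could be called differed between classes, these shares describe called cells only. Without the quality filter the melanoma-like share was 11.98% and the neutrophil-like share 1.91%.

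Within T cell-like cells, 52.1% were CD8 cells and 12.9% CD4 cells, 2.04% held both and 33.0% neither, the last with a median of 14334 counts. The CD8 share ranged from 44.6% in A0305 to 73.1% in A0304. Of 4111 CD8 cells, 17.1% were Tcf7-positive without Havcr2, 29.0% were Havcr2-positive without Tcf7 and 0.803% held both. The Tcf7-positive share was 20.5% in A0301, 18.7% in A0302, 11.9% in A0303, 7.84% in A0304, 19.6% in A0305 and 17.7% in A0306. At the same gate Tcf7 was found in 17.9% of CD8 cells (median 28269 counts) and in 5.71% of melanoma-like cells, which should lack it (median 193426 counts). Havcr2 was found in 29.8% of CD8 cells and in 4.04% of melanoma-like cells. The gates were less selective against myeloid barcodes. In macrophage-like and dendritic cell-like barcodes Tcf7 was found in 13.7% and 10.6% and Havcr2 in 41.4% and 24.3% (medians of 73483 and 51414 counts). Havcr2 was thus found in a larger share of macrophage-like barcodes than of CD8 cells. Myeloid barcodes often held T cell genes, as described below. Whether their Tcf7 and Havcr2 counts came from T cells or from the myeloid cells themselves was not tested. Of 1014 CD4 cells (median 23179 counts) 29.8% were Foxp3-positive (27.0 to 32.7), against 1.87% of CD8 cells.

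**Figure D1:**
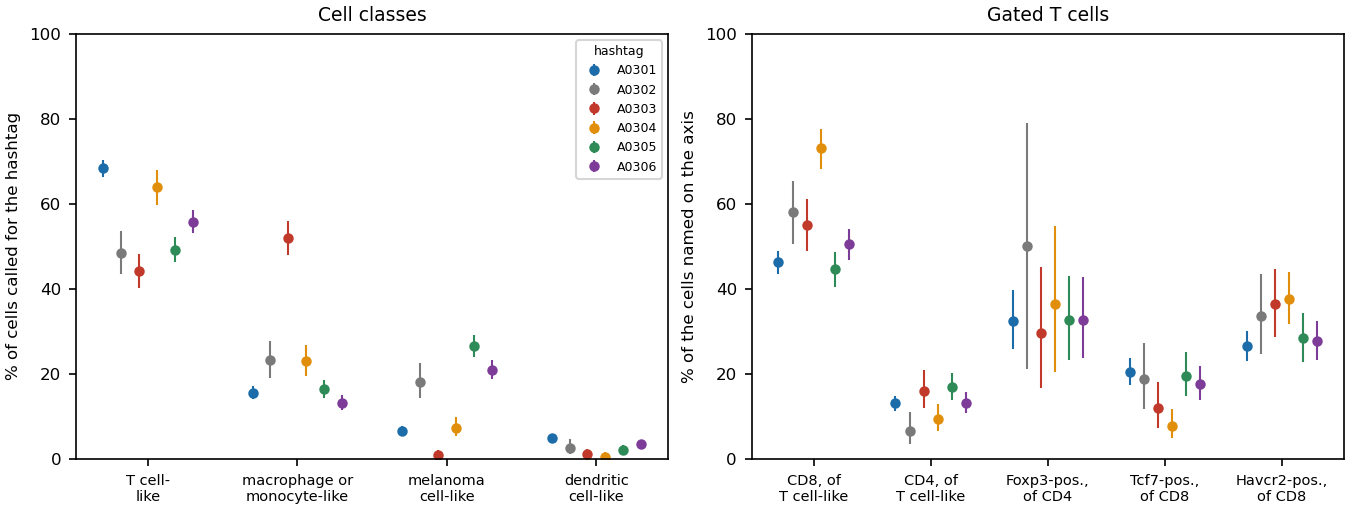
Share of called cells in each class (left) and of gated T cells (right) for each of the 6 hashtags, in percent; points are hashtags and bars exact 95% binomial intervals, which cover counting error only. The macrophage-like share of A0303 stands at 51.9%, and the Tcf7-positive share of CD8 cells runs from 7.84% to 20.5%.

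Tcf7-positive CD8 cells had higher progenitor or memory genes (14 of 17 examined) and lower cytotoxic genes (14 of 18) than Havcr2-positive cells. The question is how CD8 cells gated on Tcf7, a gene of precursor-like cells, differ from those expressing Havcr2, the gene for the inhibitory receptor TIM-3. Of 703 Tcf7-positive cells 474 held no Pdcd1 count, so the arm may hold other cells than precursors of exhausted cells. With Pdcd1 required in that arm and all cells pooled, an alternative added later, 232 of the 636 calls reported below were shared. Of those 636, 612 kept their sign. Tcf7 lies on chromosome 11 from 52252371 to 52283014 and Havcr2 on chromosome 11 from 46454935 to 46481255, both protein-coding. Klf2, a transcription factor of T cell quiescence and migration, was higher in Tcf7-positive cells by a median log2 of 5.00 (4.44 to 5.01 over 3 hashtags), Slamf6, a surface marker of precursor-like cells, by 4.37 (2.72 to 4.81) and S1pr1, a receptor for exit from tissue, by 4.36 (2.87 to 4.70). Nsg2 (5.50, 3.00 to 7.64), Dapl1 (5.00, 4.65 to 5.03), Fam241a (3.44, 3.39 to 4.83), Klf3 (3.31, 2.44 to 6.42), Rgs10 (3.24, 1.52 to 3.37) and Cmah (3.18, 2.82 to 3.24) were also among the 10 highest ratios. The lowest were the chemokine gene Ccl3 (-5.14, -5.66 to -2.73), Spp1 (-5.01, -6.40 to -3.20), the granzyme gene Gzmf (-4.64, -5.49 to -3.98), the growth factor gene Csf1 (-4.10, -4.69 to -1.36), Adam8 (-3.68, -3.90 to -2.02), the metallothionein gene Mt1 (-3.55, -3.78 to -2.30), perforin Prf1 (-3.36, -4.04 to -2.64), Gzmb (-3.35, -4.61 to -3.09), AA467197 (-3.26, -4.01 to -2.12) and Lat2 (-3.16, -3.57 to -0.75). With a hashtag left out, Nsg2 was at 4.25 (without A0301) to 6.57 (without A0305), Klf3 at 4.86, Ccl3 at -3.93, Spp1 at -4.11, Adam8 at -2.85 and Slamf6 at 3.55 (without A0305). Without A0306 Csf1 was at -2.73, Mt1 at -2.93, S1pr1 at 3.62, Fam241a at 4.14, Rgs10 at 2.38 and Spp1 at -5.71, and without A0301 Lat2 was at -1.96 and Gzmb at -3.98.

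Of 17 progenitor or memory genes examined, 14 were called higher in Tcf7-positive cells and 0 lower. Of 18 cytotoxic genes, 14 were lower, among them Gzmc (-5.24, and -4.23 without A0301), Ccl3 and, at or under the floor of 30 counts in the Tcf7-positive arm, Gzmd (at least 20.2-fold lower over the hashtags summed) and Gzme (at least 19.99-fold lower over the hashtags summed, -5.67 to -3.77 in each); these granzyme genes are close copies and their reads may be split between them. Among 7 inhibitory receptor genes, Entpd1 (-5.13), an ectonucleotidase, and Lag3 (-1.76) were lower. Pdcd1 stood at -0.99 and Ctla4 at -0.87 without a call, and with a hashtag left out they reached -1.02 and -1.27. Of 11 exhaustion transcription factors Id2 (-2.15), Tbx21 (-1.57) and Prdm1 (-1.49) were lower and Eomes (1.10) higher, the last at 0.85 without A0301. The NR4A genes were not called: Nr4a3 was at 0.60 (0.43 to 1.47), Nr4a1 at 0.13 and Nr4a2 at -0.50. With a hashtag left out Nr4a3 reached 1.04, past the size needed for a call. Of 14 activation-induced genes Cd69 (1.53) and Jun (1.51) were higher and Tnfrsf9 (-2.01) lower.

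Of 18 proliferation genes 7 were lower, with Ccnb1 at -2.41, Tpx2 at -1.41, Cdk1 at -1.39 and Ccna2 at -1.25; without cells holding Mki67 or Top2a, Cdk1 was at 0.91 and Tpx2 at 0.20, and with Slamf6 in place of Tcf7 Ccna2 was at 0.24. Of 13 glycolysis and hypoxia genes 6 were lower, led by Slc2a3 (-1.78) and Bnip3 (-1.42), the latter at -0.96 without A0305 and -2.05 without A0306. Aldoa, lower at -1.11, was at -0.95 with a hashtag left out, under the size needed for a call. Among 7 residency and homing genes 2 were lower, with Cxcr6 at -2.82, and Itgb7 (2.34) was higher. Of 9 helper genes examined 5 were higher, among them Slamf6, Ccr7 (3.03) and Cxcr3 (2.80), and 2 were lower, with Ifng at -2.95. Of 13 regulatory T cell effector genes 7 were lower and Ikzf2 (1.602) was higher. None of 8 interferon-stimulated, 4 NK receptor, 5 heat shock and 10 ribosomal protein genes was called; all 10 ribosomal protein genes lay above 0, with Rps27 at 0.97.

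In all, 636 of 5892 genes were called, 291 higher and 345 lower, and 52.0% had the same sign in all 3 hashtags, where chance gives 25%. Tcf7-positive cells were shallower (median 23507 counts against 44600) and lay mostly in clusters 1 (led by Klra genes), 2 and 12 (41.3%, 22.6% and 18.8%), Havcr2-positive cells in clusters 0 and 3 (50.2% and 37.1%). B cell marker genes summed to 58.7 CPM against 11.998 and endothelial genes to 35.3 against 9.01, while macrophage genes stood at 188 against 177. Plasmacytoid dendritic cell genes, which include Bst2 of the interferon-stimulated list, stood at 237 against 683. A call needed the same sign in every hashtag used, so counts of calls from other numbers of hashtags or genes are not comparable: 344 of 2928 genes were called without cells holding Mki67 or Top2a (3 hashtags), 285 of 8058 with gates on any cell with Cd3 counts (4 hashtags), 408 of 5998 with Slamf6 in place of Tcf7 (2 hashtags) and 364 of 4861 with 10 or more cells per arm (6 hashtags).

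**Figure D2:**
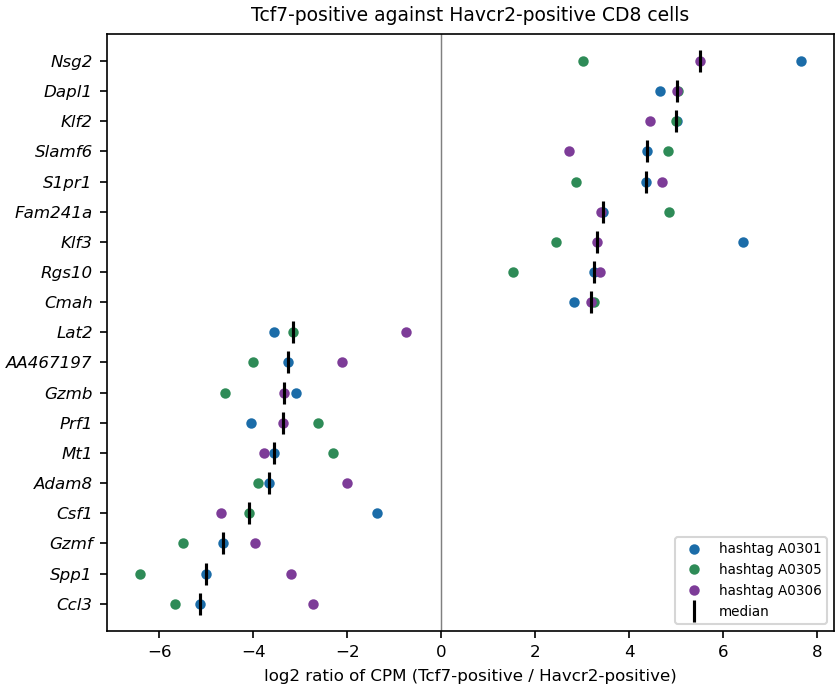
Log2 ratio of CPM between Tcf7-positive and Havcr2-positive CD8 cells for genes named among the 10 highest and 10 lowest; coloured points are the 3 hashtags and black ticks their medians. Nsg2 stands at a median of 5.50 and Ccl3 at -5.14.

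Foxp3-positive CD4 cells had higher regulatory genes and less Ifng than Foxp3-negative CD4 cells. Foxp3, the lineage factor of regulatory T cells, lies on chromosome X from 7573644 to 7595245. Lrrc32, which presents latent TGF-beta on regulatory T cells, was higher by a median log2 of 3.52 (3.18 to 5.76 over 3 hashtags), Ikzf2, a transcription factor of these cells, by 2.52 (2.47 to 3.10) and Il2ra, an interleukin receptor chain, by 2.48 (2.04 to 2.54). Gm6637 (4.02, 2.37 to 4.21), Klrg1 (2.73, 2.71 to 2.89), Ctsz (2.54, 1.77 to 2.77), Slc16a3 (2.49, 1.94 to 2.49), Neb (2.46, 1.86 to 2.98) and Arl5c (2.19, 1.71 to 2.38) were also among the 10 highest. The lowest were Tnfsf11 (-4.45, -4.82 to -3.24), Tnfsf8 (-4.33, -5.11 to -1.44), the cytokine gene Ifng (-4.01, -4.55 to -3.55), Tbc1d4 (-3.93, -5.82 to -2.64), Dusp6 (-3.71, -4.75 to -0.93), Klrd1 (-3.59, -4.42 to -2.89), Ece1 (-3.46, -3.69 to -1.80), Ms4a4b (-3.25, -3.78 to -2.37), Penk (-3.19, -3.66 to -1.22) and AA467197 (-3.08, -3.60 to -1.08). With a hashtag left out, Tnfsf8 was at -2.89 (without A0306), Dusp6 at -2.32 and Penk at -2.21 (without A0305), Ece1 at -2.63 (without A0306), AA467197 at -2.08, Tnfsf11 at -3.85, Tbc1d4 at -4.88 and Lrrc32 at 4.64 (without A0301) and Gm6637 at 3.19 (without A0305); Penk was at -1.22 with all cells pooled.

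Of 17 regulatory T cell effector genes 13 were higher and 1 lower. Of 9 helper genes 3 were lower, Ifng, Bhlhe40 (-1.50) and Lef1 (-1.33). Among 6 inhibitory receptor genes Ctla4 (1.70) and Tigit (1.00) were higher. Of the NR4A family Nr4a2 was lower (-1.95), and Nr4a3 (-0.92, and up to -1.19 in size with a hashtag left out) and Nr4a1 (-0.29) were not called. Of 15 activation-induced genes Tnfrsf9 (1.59) was higher, and Fosb (-1.48), Dusp2 (-1.40, and -2.12 without A0306) and Egr1 (-1.26) were lower. Among exhaustion transcription factors Prdm1 (1.99) was higher and Bhlhe40 lower. Of 15 progenitor or memory genes 4 were higher, with Ikzf2, and 2 lower, with S1pr1 (-1.44, -3.82 to -1.26, and -2.63 without A0305). Cytotoxic genes included 4 lower of 11, and Klrg1 higher; Gzma was at -4.82 (-5.81 to -1.99), but at -3.41 without A0306 and at -1.91 with all cells pooled. Both NK receptor genes examined were lower, Klrc1 at -4.14 (-4.96 to -3.43), and at -3.97 with all cells pooled. Of 7 residency and homing genes 2 were higher, with Ccr2 at 1.69, and Cxcr6 (-1.48, and -2.13 without A0306) was lower; Cenpf (1.26, and 2.82 without A0305) and Tpx2 (1.16) were higher among 18 proliferation genes, and 1 of 7 interferon-stimulated genes was higher. None of 11 glycolysis, 5 heat shock and 10 ribosomal protein genes was called. With a hashtag left out, Tigit (0.87), Tpx2 (0.91), Cenpf (0.93) and Lef1 (-0.80), each without A0306, were under the size needed for a call.

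Of 3759 genes 258 were called, 114 higher and 144 lower, and 39.96% had the same sign in all 3 hashtags, where chance gives 25%. Foxp3-positive cells were deeper (median 32440.5 counts against 18868.5). They lay mostly in clusters 6 and 11 (62.6% and 34.4%), and Foxp3-negative cells in clusters 2 and 8 (42.6% and 32.7%). The leading genes of cluster 11 included Mki67 besides Igha, Igkc and Jchain, the last found in 0.397% of its cells. Macrophage genes, which include Ccr2, summed to 598 CPM in Foxp3-positive against 232 in Foxp3-negative cells. B cell genes summed to 106 against 29.3 and plasma cell genes to 2.24 against 243. How many cells carried the plasma cell genes was not counted. After thinning the split was 112 higher and 86 lower. Ccl3, called lower at -2.02 (-3.09 without A0301, -1.08 without A0306), was at 0.40 after thinning, and Dusp6 was at 1.10 and Cenpf at -0.66 without cells holding Mki67 or Top2a, where 1 hashtag remained. With other numbers of hashtags and genes, 163 of 2976 genes were called with 10 or more cells per arm (5 hashtags), 400 of 6627 with all cells pooled (no sign needed) and 454 of 3412 without T cells holding macrophage or melanoma counts (1 hashtag).

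CD8 cells differed from Foxp3-negative CD4 cells in cytotoxic and NK receptor genes. Cd8a lies on chromosome 6 from 71373427 to 71379173 and Cd4 on chromosome 6 from 124864692 to 124888221. Prf1, the pore-forming protein perforin, was higher in CD8 cells by a median log2 of 4.35 (3.66 to 4.97 over 4 hashtags), the lectin-like receptor gene Klre1 by 4.33 (3.25 to 5.12), Cd160 by 3.22 (2.03 to 3.59) and granzyme B, Gzmb, by 2.87 (2.15 to 3.81). Atp8b4 (3.24, 2.17 to 3.83), Ly6c2 (3.15, 2.73 to 5.33), Spry2 (2.76, 0.90 to 3.64), Klrk1 (2.68, 2.04 to 2.90), Klrd1 (2.54, 2.20 to 2.64) and Fcer1g (2.49, 1.76 to 2.52) completed the 10 highest. The lowest were the TNF superfamily gene Tnfsf8 (-4.65, -8.20 to -3.67), Penk (-4.49, -7.94 to -2.78), Wisp1 (-3.72, -3.87 to -3.14), St6gal1 (-3.67, -4.38 to -2.85), Tnfsf11 (-3.38, -4.42 to -2.40), Tbc1d4 (-3.38, -4.79 to -1.43), Igfbp7 (-3.03, -3.59 to -1.95), Tiam1 (-2.92, -3.41 to -2.54), Il1r2 (-2.83, -3.62 to -1.37) and Timp2 (-2.62, -2.83 to -2.09). With a hashtag left out, Gzmb was at 2.18 (without A0303 or A0305) to 3.57, Prf1 at 3.75 to 4.95, Klre1 at 3.69 to 4.97 and Tnfsf8 at -5.26 to -4.05 (the smaller size without A0303 or A0306), and Penk at -5.17 to -3.82 (the latter without A0303 or A0305).

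Of 19 cytotoxic genes 10 were higher and 0 lower, with Gzmf at least 43.5-fold (4.52 to 5.99 as log2 in each hashtag) and Gzmd at least 13.001-fold higher (1.98 to 5.06) over the hashtags summed, and all 5 NK receptor genes examined were higher, Klrc1 by 2.25. Among 9 inhibitory receptor genes Cd160, Lag3 (1.55) and Pdcd1 (1.05) were higher and Btla (-2.13) lower. Nr4a2 was higher (1.19, 0.67 to 1.33), while Nr4a3 (-0.44) and Nr4a1 (-0.02) were not called. Slamf6 (-1.66), S1pr1 (-1.49) and Cxcr3 (-1.11) were lower and Xcl1 (2.45) higher among 17 progenitor genes; Slamf6 and Cxcr3 were also the 2 helper genes lower of 10. Of 17 activation-induced genes Tnfrsf9 (1.02) was higher, Cd83 (-2.15) and Fos (-1.30) lower. Hif1a (-1.20) and Tox2 (-1.07) were lower among 12 exhaustion transcription factors, Slc2a3 (1.26) was higher among 13 glycolysis genes, and of 8 residency genes 1 was higher and Itgb7 (-1.39) lower. Of 16 regulatory T cell effector genes 2 were higher and 3 lower, with Izumo1r at -1.74 and Tnfrsf4 at -1.59. None of 18 proliferation, 10 interferon-stimulated, 5 heat shock and 10 ribosomal protein genes was called. With a hashtag left out, Pdcd1 (0.89) and Cxcr3 (-0.98), without A0301 or A0305, Hif1a (-0.94, without A0301 or A0306), Tox2 (-0.99, without A0305 or A0306), Tnfrsf9 (0.95, without A0303 or A0306) and Slc2a3 (0.97, without A0303 or A0305) were under the size needed for a call.

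Of 7491 genes 121 were called higher and 185 lower, and 23.8% had the same sign in all 4 hashtags, where chance gives 12.5%. After thinning each cell to 8000 counts the split was 67 higher and 239 lower. With other numbers of hashtags and genes, 470 of 7714 genes were called without A0305 (3 hashtags), 620 of 9950 with gates on any cell with Cd3 counts (3 hashtags), where Timp2 was at 0.13, and 584 of 9864 with all cells pooled (no sign needed). NK cell markers, which include Klre1 and Fcer1g named above, summed to 310 CPM in CD8 and 57.2 in CD4 cells. Plasmacytoid dendritic cell genes, which include Bst2 of the interferon-stimulated list, summed to 526 against 219, and plasma cell genes to 3.66 against 243. These sums alone do not show cells of those types.

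**Figure D3:**
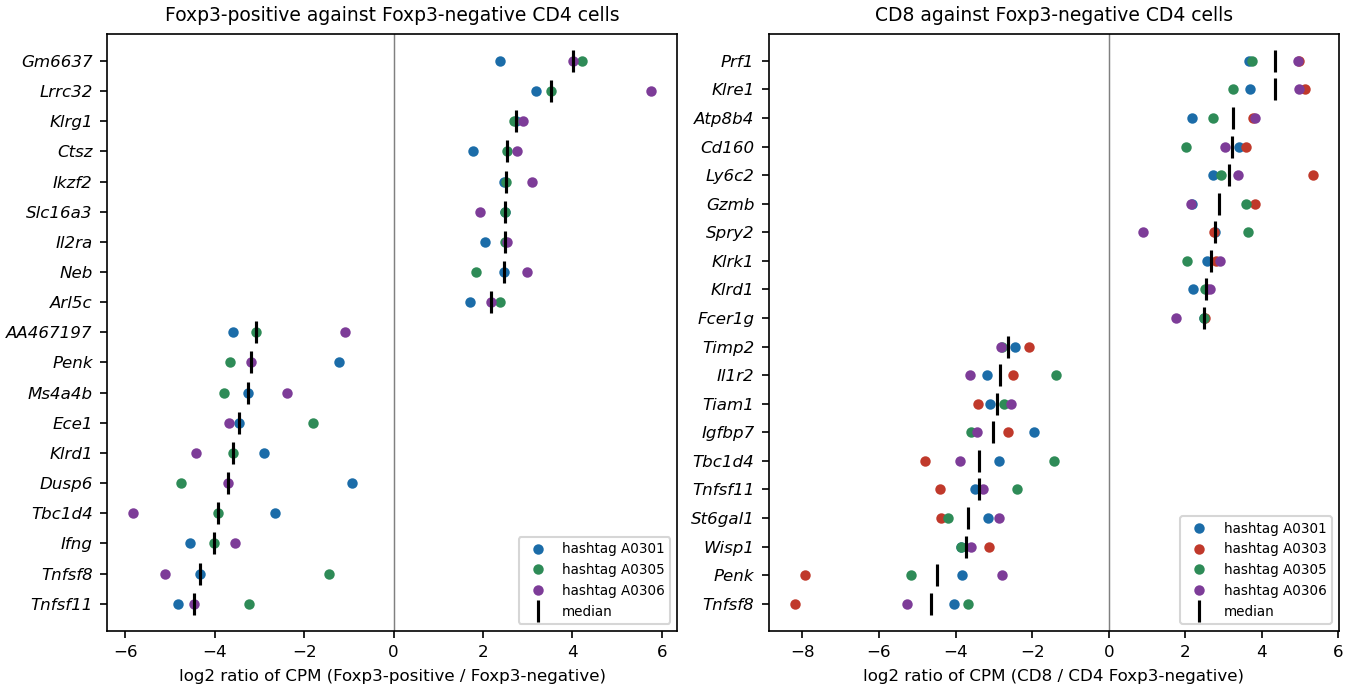
Log2 ratio of CPM for genes named among the 10 highest and 10 lowest in Foxp3-positive against Foxp3-negative CD4 cells (left, 3 hashtags) and CD8 against Foxp3-negative CD4 cells (right, 4 hashtags); coloured points are hashtags and black ticks medians. The highest medians are Gm6637 (4.02) and Prf1 (4.35).

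The Nr4a genes were measured in every hashtag. Nr4a1, on chromosome 15 from 101254269 to 101274795, stood at 188, 296, 280, 225, 213 and 247 CPM in CD8 cells of A0301 to A0306. Nr4a2, on chromosome 2 from 57106830 to 57124003, stood at 1218, 1487, 2021, 1571, 1347 and 1437 CPM, and Nr4a3, on chromosome 4 from 48045153 to 48086447, at 224, 239, 213, 189, 240 and 250 CPM. Which part of each gene was deleted is not given in the sources used here, and the library may read outside it, so these counts check nothing about the genotype of a hashtag. Tcf7 stood at 126, 116, 67.1, 47.7, 141 and 103 CPM in CD8 cells. In Foxp3-negative CD4 cells the medians over hashtags were 249.6 CPM for Nr4a1 (91.0 to 334), 820 for Nr4a2 (533 to 1626), 295 for Nr4a3 (144 to 437) and 212 for Tcf7 (149 to 332). In Foxp3-positive CD4 cells they were 159.98 for Nr4a1 (122 to 414), 262 for Nr4a2 (102 to 697), 136 for Nr4a3 (91.8 to 159.9) and 13.1 for Tcf7 (0 to 48.2), with 6 to 61 cells per hashtag. At the gate Nr4a2 was found in 80.1% and Nr4a1 in 40.4% of CD8 cells (median 28269 counts), against 15.7% and 63.1% of melanoma-like cells (median 193426 counts).

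**Figure D4:**
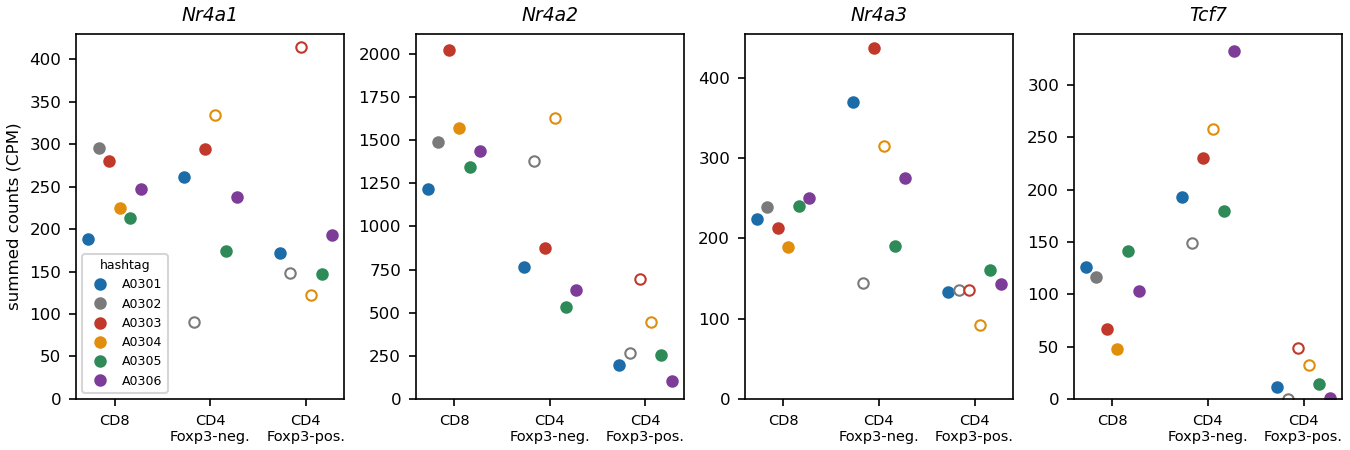
Summed counts (CPM) of Nr4a1, Nr4a2, Nr4a3 and Tcf7 in CD8, Foxp3-negative CD4 and Foxp3-positive CD4 cells for each of the 6 hashtags; filled points rest on at least 30 cells and open points on fewer. Nr4a2 in CD8 cells runs from 1218 to 2021 CPM.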

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

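The test of random pairing in a well and the condition that voided the test of hashtag pairs were chosen only after the results were seen; the other tests were set beforehand. Among 28 sets of 6 hashtag values, 4 had a value far from the others, where chance gives about 1 in 20 sets (1.4 expected), so part of them may be chance; the weighed pattern below rests on 56.3% of barcodes, tested at 6.31% in melanoma-like cells.

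Macrophage or monocyte-like cells were 51.9% of the cells called for A0303 (322 of 620), against 13.2% to 23.2% in the other hashtags. Foxp3-positive cells were 50% of CD4 cells in A0302 (6 of 12 cells), against 29.5% to 36.4% elsewhere. CD8 cells holding both Tcf7 and Havcr2 were 3.53% in A0304 (9 of 255), against 0 (upper limits up to 3.39%) to 1.04% elsewhere, with a median of 74246 counts in those 9 cells. Nr4a1 stood at 414 CPM in the 13 Foxp3-positive CD4 cells of A0303, against 122 to 193 CPM elsewhere. Hashtags A0307 to A0312, which the labels do not list, were called in 146 barcodes, 21 to 28 for each.

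T cell genes were frequent in myeloid barcodes: Cd8a was at the gate in 56.3% of macrophage or monocyte-like barcodes (53.8 to 58.8, median 73483 counts) and Foxp3 in 34.6% of dendritic cell-like barcodes (28.9 to 40.7, median 51414 counts), while Foxp3 reached 2.56% of the former and Cd8a 20.2% of the latter. Free T cell RNA would keep a constant ratio of Cd8a to Foxp3 in every type, but that ratio was 52.8 to 132 times higher in barcodes gated on macrophage genes than in those gated on dendritic genes, in the 2 hashtags with 20 or more of the latter; in A0304, with 5 such barcodes, it was 2.99 times higher. That contrast rests largely on the same barcodes as the shares above, so it argues only against free RNA as the sole source. Random pairing in a well was likewise argued against only as the sole source. Cd8a was at the gate in 6.31% of melanoma-like barcodes (median 193426 counts), if these are taken to pair as macrophage-like ones do. For pairs formed after staining, 7.11% of the Cd8a-carrying macrophage-like barcodes had 2 hashtags, against 10.4% in simulated pairs; the rule set beforehand would have favoured pairing, but barcodes without T cell genes already passed its limit at 5.23%, so it was taken as undecided once that value was seen. T cells attached to myeloid cells, which selection on CD3 would retain, are a candidate explanation that was not tested.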

How the results depend on the processing

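Alternatives marked as added were chosen only after the data had been seen. A call needed the same sign in every hashtag used, so counts from different numbers of hashtags or genes examined are not comparable. Median-of-ratios scaling, doublet removal, pooled hashtag sums (no sign needed) and no quality filter left the 3 counts of called genes within 1.5 times. Leaving out each hashtag, with a sign needed in 1 hashtag fewer, gave 582 to 851 genes for Tcf7-positive against Havcr2-positive cells, 296 to 385 for Foxp3-positive against Foxp3-negative cells and 359 to 470 for CD8 against CD4 cells, the last highest without A0305. The lower expression minimum gave 1589, 996 and 1305 genes, with more genes examined. For Tcf7 against Havcr2, the count was 344 without cells holding Mki67 or Top2a (3 hashtags, 2928 genes), 285 with gates on any Cd3 count (4 hashtags), 408 with Slamf6 (2 hashtags) and 364 with 10 or more cells per arm (added, 6 hashtags). For Foxp3 it was 497 at the gate of 10 counts, 396 without cells holding Mki67 or Top2a, 520 with stricter hashtag calls (added) and 454 without cells holding macrophage or melanoma counts (added), where 1 hashtag remained in each; it was 400 with all cells pooled (no sign needed) and 163 with 10 or more cells per arm (5 hashtags; both added). For CD8 against CD4 it was 620 with gates on any Cd3 count (3 hashtags) and 584 with all cells pooled (added, no sign needed). Thinning split the Foxp3 calls into 112 higher and 86 lower against 114 and 144, and the CD8 against CD4 calls into 67 and 239 against 121 and 185, where the median of all genes moved from -0.06 to -0.18.

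Named values that reversed were, without cells holding Mki67 or Top2a, Cdk1 (0.91) and Tpx2 (0.20) for Tcf7 against Havcr2 and Ccl3 (0.0847), Cenpf (-0.66) and Dusp6 (1.10) for Foxp3; with Slamf6, Ccna2 (0.24) and Tpx2 (0.0257); with Pdcd1 in the Tcf7-positive arm (added), Ccna2 (0.19) and Tpx2 (0.19). For Foxp3, Ccl3 was at 0.0131 with the gate at 10 counts, 0.40 after thinning and 0.15 without cells holding macrophage or melanoma counts (added), where Dusp6 was at 0.51. Timp2 was at 0.13 with gates on any Cd3 count. The cause of these changes was not tested. Of the other values for single genes, 567 moved beyond the SD over hashtags and 2320 did not; a further 899, with a hashtag left out or the lower expression minimum, could not move beyond it by construction and show nothing about stability. Without the quality filter the shares were 65.7% T cell-like, 11.98% melanoma-like, 1.91% neutrophil-like and 3.89% unnamed; unnamed cells were 3.43% at the higher resolution. Nr4a3 had any count in 47.8% of CD8 cells after thinning (median over hashtags) and 5 or more counts in 42.9% without it, so depth and threshold changed together; with any count in both, thinning lowered the share in all CD8 cells from 60.6% to 48.0%. The genotype comparison with edgeR and its alternatives (DESeq2, no low-count filter, each hashtag left out) and the check of cell names, also in cells with at least 10 hashtag counts, were not run, since no source used here gives the genotype of a hashtag or the hashtag in a cell name. No paired analysis was possible because the 2 samples are the mRNA and hashtag libraries of the same capture, which are not compared, and no genotype is known for a hashtag; the arms themselves were paired by hashtag, as ratios within each and without a test.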

Other observations

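The split of Tcf7-positive cells by Pdcd1, its values within clusters and the values per hashtag of macrophage-like and melanoma-like cells were chosen after the data had been seen. The 3 tests of the values per hashtag were set before their results, but the condition that voided the test of hashtag calls was set after. Of 703 Tcf7-positive CD8 cells, 153 also held Pdcd1, the gene for PD-1 (21.8%, 95% interval 18.8 to 25.001, and 15% to 28.6% over hashtags). Pdcd1 was at the gate in 2.27% of melanoma-like cells (median 193426 counts, against 23507 in Tcf7-positive cells). In macrophage-like and dendritic cell-like barcodes it was found in 36.3% and 17.9%. Against the 474 cells with no Pdcd1 count, over all cells with or without a hashtag call, they had higher Tox (1.38), an exhaustion factor, Lag3 (1.55), Nrp1 (1.75), Cd83 (2.39), Nr4a2 (0.79) and the cyclin gene Ccna2 (2.33). Lower were Klf2 (-2.39), S1pr1 (-2.30), Satb1 (-1.83), Lef1 (-1.68) and Il7r (-1.07), while Ccr7 (0.54), Slamf6 (0.62) and Xcl1 (0.81) were higher. Each of these had the same sign in A0301, A0305 and A0306. The gate picks deeper cells (median 46650 against 21235.5 counts), and the groups lay in different clusters. Cluster 12, led by genes that include Dapl1, Ccr7, Xcl1 and Slamf6, held 36.6% of the former and 10.1% of the latter, cluster 3, which Mki67 and Top2a help define, 31.4% and 2.74%, cluster 2 11.8% and 26.2%, and cluster 1, led by Klra genes and of unsettled identity, 10.5% and 55.9%. Within cluster 12, the only 1 of these with 30 or more cells in both groups (56 and 48), every ratio was smaller: Nr4a2 was at -0.01, Ccr7 at 0.12, Slamf6 at 0.17, Ccna2 at 0.24 and Xcl1 at 0.32, and Il7r turned to 0.36. There Tox was at 0.59, Lag3 at 0.56, Nrp1 at 0.96, Cd83 at 0.81, Klf2 at -0.88, S1pr1 at -0.92, Satb1 at -0.83 and Lef1 at -1.03. In clusters 1, 2 and 3, with 16, 18 and 13 cells in the smaller group, sizes went both ways. Lag3, for example, was at 2.87 in cluster 1 and 0.26 in cluster 3. The ratios over all cells are thus in part differences between clusters; how large a part is open, since the clusters were drawn from the same counts.

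The interferon-stimulated genes of the fixed list summed in melanoma-like cells of A0301 to A0306 to 1304, 817, 2955, 2589, 820 and 714 CPM, but in macrophage-like cells only from 1420 (A0305) to 2627 (A0304), with A0303 at 2249 and A0301 at 2106. Further genes were chosen after the values had been seen. B2m, a component of MHC class I, stood in melanoma-like cells at 6042, 4248, 12607, 11803, 4686 and 4608 CPM. In CD8 cells it stood at 5749, 5944, 6863, 6450, 5858 and 5931 CPM. Cxcl9, an interferon-induced chemokine, stood in macrophage-like cells at 954, 264, 1629, 1472, 548 and 727 CPM. Ifng in CD8 cells stood at 422, 525, 1092, 517, 343 and 348 CPM. A0303 held 6 melanoma-like cells.

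Cluster shares are given here only because they are the values tested. The cluster of macrophage-like cells led by Gbp2b and Cxcl13 held 21.6%, 19.3%, 82.6%, 66.7%, 16.0% and 14.4% of the macrophage-like cells of A0301 to A0306, and that of melanoma-like cells led by Ubd and Iigp1 held 16.4%, 4.35%, 83.3%, 67.5%, 3.97% and 4.53%. Macrophage-like barcodes of A0303 and A0304 were also deeper, with medians of 93616 and 97160 counts, against 61284 to 69974 in the other hashtags. Among cells with 20 or more hashtag counts A0303 stood at 83.3%, and A0302, the hashtag set beforehand for comparison, at 27.1% (15.3 to 41.8). That test cannot settle differences in which cells are called. A0303 and A0304, the hashtags richest in these clusters, had the least background of the 6 (1.90% and 2.73%), and A0302 had 5.65%. T cell reads in the same barcodes were argued against only as the sole source. Without barcodes holding T cell gate genes A0303 stood at 80.6%, against 11.1% (2.35 to 29.2, 3 of 27 barcodes) in A0302. That filter lowered the share in every hashtag, as from 16.0% to 7.35% in A0305. It used Cd8a, Cd8b1, Cd4 and Foxp3 only, so barcodes with other T cell genes could remain. Wrong hashtag calls stay open: stricter calls left A0303 at 82.6%, but they kept 319 of its 322 macrophage-like cells, dropped 3 and added 8, and so tested little. No biological explanation was tested, since the labels give no genotype or animal for a hashtag, and none was inferred.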
